A study of Mus musculus with 2 samples.

How the data were processed

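The data are a table of miRNAs expressed in 2 small RNA libraries of mouse serum exosomes. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the TruSeq Small RNA kit and sequenced on an Illumina HiSeq 2500, and reads were filtered with ACGT101-miR to remove adapter dimers, junk and low-complexity reads, other RNA families and repeats. Per the labels, the extraction text speaks of 9 libraries and names 6, while 2 samples are listed, and whether the libraries are pools of animals is not given in the sources used here. Genome build, miRBase version and aligner are likewise not given in the sources used here.

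The raw columns hold expected counts: per the file headers they are numbers of reads at the 5' or 3' end of a precursor, and reads that fit several places appear divided between them, so that values need not be whole. The normalized columns hold a signal deposited by the authors that equals each raw value times 1 constant per library (0.941 for dEXO and 1.06 for EXO), and the rule behind the constants is not given in the sources used here. The table had 705 rows with values, 587 of known mouse precursors and 118 of predicted hairpins, and 20 further lines are not used here. Of 399 mouse precursor positions, 395 have the same coordinates in GENCODE release M21, so coordinates are those of the table and equal GRCm38 positions. All columns of values were used.

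The design fixed before the data were examined counted rows that repeat a mature sequence once, on the assumption that they held the same reads. The table divides the reads of such a sequence evenly between its rows (43 sequences, equal in every row to within 1e-06, many with values ending in fractions of a read). These rows were therefore summed, which gave 649 distinct sequences and counts each read once. Taking 1 row without summing was an alternative chosen after seeing the data. Names are given without the species prefix and without the suffix that marks a length or base variant. Where sequences of several precursors are identical the reads cannot be assigned to 1 of them, which applies to miR-1a-3p, miR-7a-5p, miR-16-5p, miR-24-3p, miR-29b-3p, miR-30c-5p, miR-128-3p, miR-133a-3p, miR-181a-5p, miR-194-5p, miR-218-5p, miR-365-3p, miR-486b-5p and let-7c-5p among those fixed by rule. miR-92a-3p is listed as a pair of entries with equal values. Entries with fractional values, such as miR-23a-3p, miR-29a-3p, miR-101b-3p and let-7g-5p, appear to share part of their reads with others. Of several entries with 1 name, lists used the most abundant.

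CPM values were computed here by scaling the deposited expected counts to the total of all entries, the depth being 1762278 for dEXO and 1796631 for EXO. A count of 3, taken as the limit that a count of 0 allows, equals 1.70 CPM in dEXO and 1.67 CPM in EXO. The ratio of dEXO over EXO was computed per entry with an exact Clopper-Pearson interval (95%) for the share of its counts in dEXO, on counts rounded to whole numbers, and log2 ratios with 1 CPM added to each library. An entry was called higher or lower where the CPM ratio was at least 2 or at most 0.5 with an interval excluding 1, among entries with a mean of at least 50 CPM and at least 50 counts in total. With 1 library per group no test was run. The count columns do not hold replicates, so the planned edgeR test on replicate columns was not run. Shares have exact Clopper-Pearson binomial intervals, and ratios of arm ratios and of the miR-451a to miR-23a-3p ratio have exact conditional intervals of an odds ratio. Arm ratios used hairpins with at least 50 counts on each arm whose sequences are listed at 1 precursor, and 19 hairpins were left out because an arm sequence is listed at several. For each of 16 fixed lists, the median log2 ratio over detected members was placed among 10000 random lists of mouse miRNAs with the same number from each of 8 bins of mean CPM. Members with 0 counts in 1 library, set to the limit of 3 counts, left each list median unchanged.

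The miRNAs named were fixed by rule before the data were examined: among mouse miRNAs past the filter the 12 highest and the 12 lowest log2 ratios, the 10 most abundant of each library, up to 4 members of each list with the highest mean CPM, the 3 highest and 3 lowest arm ratios and the 3 most abundant predicted entries. Further list members and the fourth hairpin past the threshold were named after their values were seen. Sequences of predicted entries were compared with their listed hairpins, with measured mouse miRNAs and with GENCODE M21 transcripts. The procedure was tested on simulated Poisson counts of dEXO against EXO, which hold counting error alone, as the intervals assume. The outcome thus checks the calculation and gives no error rate for real libraries. Of 268 simulated miRNAs past the filter, 94.4% had the true fold inside the interval. Of these miRNAs, 0% of 181 unchanged ones and of 26 changed 1.5-fold were called. All (100%) of 28 changed 3-fold and of 33 changed 6-fold were called. Of 200 unshifted random lists 3.5% fell outside percentiles 2.5 to 97.5.

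Alternatives were TMM factors from edgeR 4.0.16 (1.08 for dEXO and 0.929 for EXO), size factors from DESeq2 1.42.0 (1.07 and 0.933), the total without the 5 most abundant miRNAs, the authors' normalized values, each row of the table taken separately, variants of a name summed, 10 CPM added, no filter, a mean of at least 500 CPM, 1.5-fold and 4-fold thresholds, mouse miRNAs alone, and 20 or 200 counts on each arm. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.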

Results

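Small RNA was sequenced from exosomes, the small extracellular vesicles, of mouse serum. The question was how a disturbed gut microbiota alters the miRNAs carried by circulating vesicles. According to the study design, 1 group of mice drank water with vancomycin at 0.5 mg/ml and neomycin, ampicillin and metronidazole at 1 mg/ml each for 4 weeks, and wild-type mice formed the other group. The data are 1 library per group, named dEXO and EXO in the table. No label states which of these names belongs to which group. The name dEXO was read as the antibiotics group and EXO as wild type, because only 1 group was in an altered state. This reading is an inference, and if it is wrong every direction with respect to antibiotics turns round, so the libraries are named dEXO and EXO throughout and directions are given as dEXO over EXO. The dEXO library held 1762278 counts and the EXO library 1796631, and 489 and 482 of 532 mouse miRNA sequences were detected in them. With 1 library per group no difference has a replicate check and no p-value is given, and the comparisons are between these libraries, not between conditions. Intervals are 95% intervals and cover counting error of reads only, not variation between animals or library preparations. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Ratios are of counts scaled to the library total (CPM). On this scale the median log2 ratio of the 246 mouse miRNAs compared was 0.28. It was lower by between 0.20 and 0.23 under 4 other scalings, so groups of miRNAs are described relative to that median. Folds of single miRNAs are on the total scale and include this common shift.

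The most abundant miRNAs were largely shared, with 1 large exception. miR-21a-5p, a widely expressed miRNA of many cell types, led both libraries with 11.2% of dEXO counts (95% exact binomial interval 11.1 to 11.2%) and 11.8% of EXO counts (11.7 to 11.8%). miR-122-5p, the most abundant miRNA of hepatocytes, made up 11.7% of EXO counts (11.6 to 11.7%) (rank 2 there) but only 0.476% of dEXO counts (0.465 to 0.486%). The muscle miRNA miR-1a-3p accounted for 4.67% of dEXO and 3.37% of EXO, and miR-143-3p of smooth muscle for 4.06% and 3.18%. The red cell miRNAs miR-451a and miR-486b-5p made up 3.26% and 2.91% of dEXO against 1.64% and 2.17% of EXO. miR-215-5p had rank 5 in dEXO at 3.25% and made up 1.54% of EXO, while its seed relative miR-192-5p had rank 3 in EXO at 3.58% and made up 1.87% of dEXO. miR-22-3p stood at 20046 CPM in dEXO and 28841 in EXO, and miR-30a-5p at 17174 and 22019. The remaining miRNAs on these lists, miR-23a-3p, miR-29a-3p, miR-142a-5p and let-7g-5p, each took between 1.63% and 2.79% of either library. In all, 6 miRNAs were on both lists of 10, and the 10 most abundant held 38.9% of dEXO counts (38.8 to 38.9%) and 46.1% of EXO counts (46.0 to 46.1%).

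**Figure D1:**
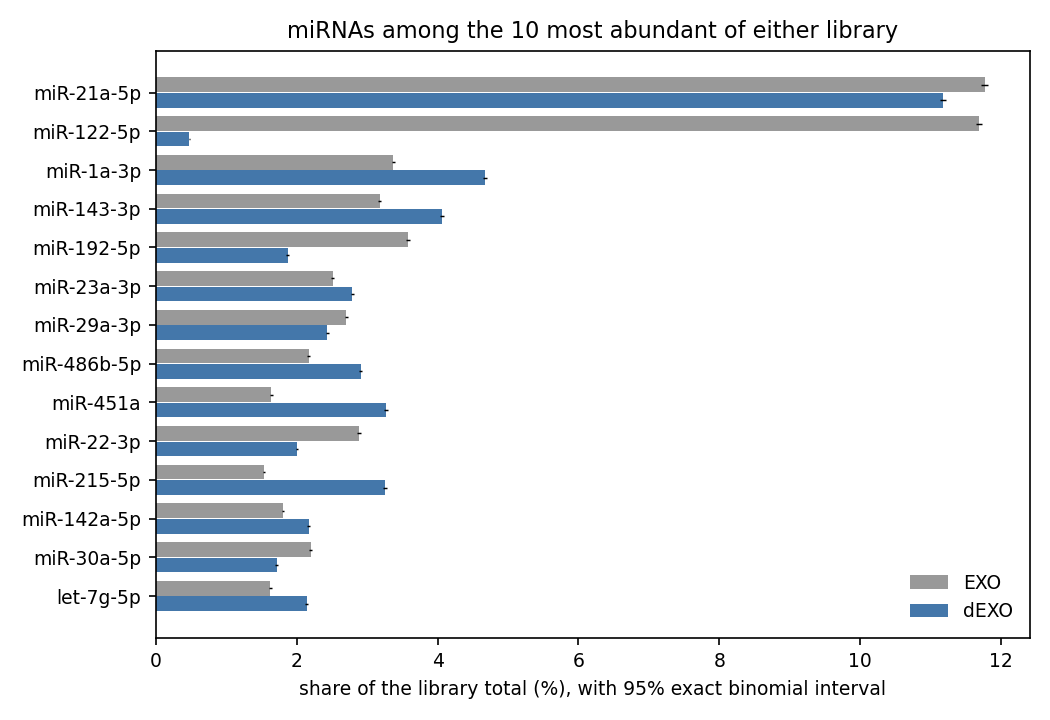
Share of the library total, in percent, of each miRNA among the 10 most abundant of either library, with exact binomial intervals (95%) as error bars, for dEXO (blue) and EXO (grey). miR-122-5p takes 11.7% of EXO and 0.476% of dEXO, while miR-21a-5p takes 11.8% and 11.2%.

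The comparison of dEXO with EXO asked which miRNAs differed by at least 2-fold beyond counting error. Both arms of the miR-122 hairpin (GRCm38 chromosome 18, 65248861 to 65248926, plus strand, Mir122) were the lowest mouse miRNAs in dEXO. miR-122-5p stood at 4756 CPM in dEXO and 116895 CPM in EXO, 24.6-fold lower (24.0 to 25.1), and miR-122-3p at 6.24 and 183 CPM, 29.2-fold lower (16.1 to 59.2). miR-193a-5p (chromosome 11, 79711969 to 79712034) was 2.92-fold lower (2.12 to 4.08), and miR-511-5p, encoded in an intron of the macrophage receptor gene Mrc1, was 2.27-fold lower (1.79 to 2.89). The others past the threshold on that side were mir-5126-p3, 6.93-fold lower (5.75 to 8.40), miR-5119 at 3.35-fold (3.01 to 3.72) and mir-6240-p3 at 2.77-fold (2.58 to 2.96). miR-192-5p, of liver and intestine, was 1.91-fold lower (1.89 to 1.94), miR-101b-3p 1.84-fold, miR-5124a 1.78-fold, miR-148a-3p 1.63-fold and miR-365-3p 1.52-fold, all short of 2-fold.

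On the other side, miR-5106 was 3.57-fold higher in dEXO (3.23 to 3.96). By its suffix this entry is a length and base variant, so its sequence differs from that of the named miRNA. The entries mir-5126-p3, miR-5124a and mir-6240-p5 are likewise base variants by their suffixes. Both arms of miR-215 (chromosome 1, 185313581 to 185313692, plus strand) were 2.11-fold (2.08 to 2.14) and 2.09-fold (1.95 to 2.25) higher for 5p and 3p. miR-199b-5p was 2.21-fold higher (1.88 to 2.60), miR-503-5p of chromosome X 2.19-fold (1.82 to 2.65) and miR-15b-3p 2.01-fold (1.82 to 2.22). Just under the threshold lay miR-451a at 1.99-fold (log2 ratio 0.99), miR-184-3p at 1.98-fold, miR-455-5p (log2 ratio 0.97), miR-142a-3p at 1.95-fold, mir-6240-p5 at 1.90-fold and miR-411-5p at 1.86-fold.

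Of 259 entries with a mean of at least 50 CPM and at least 50 counts in total, 6 were at least 2-fold higher in dEXO and 15 at least 2-fold lower, with intervals excluding 1. All 6 higher entries and 7 of the lower ones were mouse miRNAs, and the other 8 lower entries were predicted hairpins. Of the 246 mouse miRNAs, 233 (94.7%) lay within a log2 ratio of -1 and 1. The split depended on the scaling: with edgeR's trimmed mean of M-values (TMM) 1 entry was higher, miR-5106, and 20 were lower. The ratios of 5 of the 6 higher miRNAs then fell under 2, while miR-192-5p, miR-101b-3p and miR-5124a passed on the lower side.

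**Figure D2:**
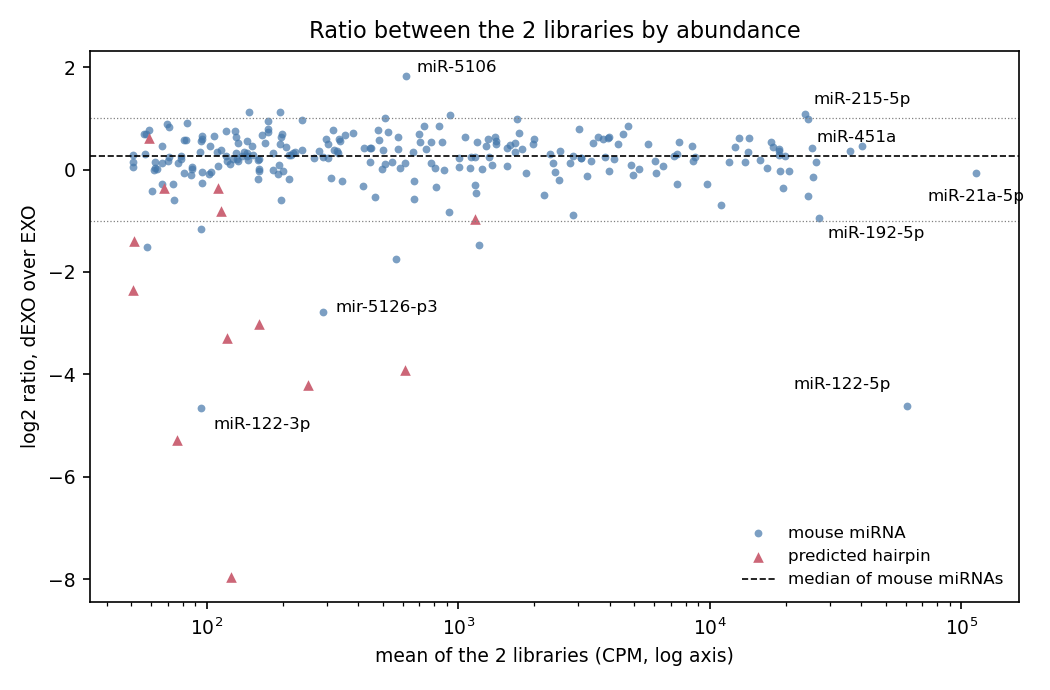
Log2 ratio of dEXO over EXO, with 1 CPM added to each library, against the mean CPM of both libraries on a log axis, for 246 mouse miRNAs (circles) and 13 predicted hairpins (triangles); the dashed line is the median of the mouse miRNAs at 0.28 and the dotted lines mark 2-fold. Both arms of miR-122 lie at log2 ratios of -4.62 and -4.66, far below the other mouse miRNAs.

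Lists of miRNAs typical of cell types, tissues and families were compared next, as markers of the sources of serum RNA. For each list the median log2 ratio is set against 10000 random lists of like abundance, as a description of these libraries. Liver miRNAs were the lowest group in dEXO. The hepatocyte list had a median log2 ratio of -0.79, 1.07 log2 units below the median of all mouse miRNAs (percentile 0, below each of the random lists). Of its 9 members past the filter, 2 were at least 2-fold lower, both of them arms of the miR-122 hairpin. Of the 9, 8 lay below the median of all mouse miRNAs. miR-148a-3p had a log2 ratio of -0.70 and miR-101a-3p of -0.20, whereas miR-194-5p, which intestine also expresses, stood at 0.51 and the liver miRNA miR-802-5p at 0.07, a value whose sign was negative under TMM.

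Red cell miRNAs were the group that stood highest among the random lists. The erythroid list had a median log2 ratio of 0.63 (percentile 99.95 of the random lists, whose median was 0.26), and 11 of its 12 members past the filter lay above the median of all mouse miRNAs. None reached 2-fold. miR-144-3p, which shares a locus with miR-451a, had a log2 ratio of 0.85, and miR-16-5p was 1.53-fold higher in dEXO. miR-25-3p was 1.36-fold and miR-486b-5p 1.34-fold higher, 0.17 and 0.14 log2 units above the median of all mouse miRNAs. The ratio of miR-451a to miR-23a-3p, used as a sign of red cell RNA in serum, was 1.17 in dEXO (1.16 to 1.18) and 0.652 in EXO (0.643 to 0.662), 1.79-fold higher in dEXO (1.76 to 1.83). This ratio within a library does not depend on the scaling.

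The miR-17-92 and paralogous clusters, proliferation-linked miRNAs that share 4 members with the erythroid list, had a median log2 ratio of 0.59 (percentile 99.18). Of 12 members past the filter, 11 lay above the median of all mouse miRNAs and none reached 2-fold. miR-93-5p was 1.63-fold and miR-106b-5p 1.52-fold higher in dEXO. miR-92a-3p, 1.18-fold higher on the total scale, lay below the median of all mouse miRNAs at a log2 ratio of 0.24.

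Epithelial miRNAs had a median log2 ratio of 0.54 (percentile 98.39), and 8 of 12 lay above the median of all mouse miRNAs. Only miR-215-5p was at least 2-fold higher in dEXO, and the other 11 lay within 2-fold. The miR-200 family, which marks epithelial cells, was 1.56-fold higher for miR-200a-3p, 1.51-fold for miR-200b-3p, 1.62-fold for miR-200c-3p and 1.48-fold for miR-429-3p. miR-194-5p was 1.42-fold higher, while miR-205-5p of stratified epithelium had a log2 ratio of -0.06 and miR-203-3p of skin -0.49. This list shares 2 members with the hepatocyte list, of which miR-192-5p stood at -0.94. With each row of the table taken separately, its percentile was 95.8, inside the range of 2.5 to 97.5.

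The miR-29 family, regulators of extracellular matrix genes, had a median log2 ratio of -0.45 (percentile 2.285), with miR-29a-3p at -0.15, miR-29b-3p at -0.45 and miR-29c-3p at -0.54. Its 3 members are few for a percentile.

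The other 11 lists lay inside percentiles 2.5 to 97.5 and had no member at least 2-fold higher or lower past the filter. Striated muscle had a median log2 ratio of 0.46 (percentile 86.7), with miR-133a-3p at 0.44, miR-206-3p at 0.65 and miR-378a-3p at -0.27. The let-7 family stood at 0.47 (percentile 89.1), all 9 members above 0 in CPM, with let-7i-5p at 0.61, let-7c-5p at 0.47 and let-7b-5p at 0.17, the last negative under TMM. The pancreatic list had a median of 0.67 (percentile 85.8), but only miR-375-3p and miR-7a-5p passed the filter, at 0.07 and 0.42, of which miR-375-3p was negative under TMM. miR-217-5p was at 9.65 and 3.34 CPM and miR-216b-5p at 6.81 and 3.90 CPM. Neuronal miRNAs stood at 0.29 (percentile 63.8), with miR-128-3p at 0.54, miR-132-3p at 0.37 and miR-218-5p at 0.32. The imprinted Dlk1-Dio3 cluster stood at 0.28 (percentile 62.2), with miR-127-3p at 0.43, miR-434-3p at 0.39, miR-136-3p at 0.28 and miR-541-5p at -0.01.

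Endothelial and vascular miRNAs had a median log2 ratio of 0.25 (percentile 52.6), with miR-143-3p at 0.36, miR-126a-5p at 0.26, miR-221-3p at 0.24 and the endothelial miR-126a-3p at 0.15, the last negative under TMM. Myeloid miRNAs stood at 0.22 (percentile 28.4), a median that was negative under 2 other scalings, with miR-223-3p of granulocytes at 0.17, negative under TMM, and miR-142a-5p at 0.26. Lymphoid miRNAs stood at 0.11 (percentile 9.84), with miR-150-5p of mature lymphocytes at 0.01 and miR-181a-5p at 0.21, both negative under TMM. The medians of the platelet list at 0.15 (percentile 20.3), the miR-30 family at 0.19 (percentile 30.8) and the inflammation list at 0.08 (percentile 6.205) were, like that of the lymphoid list, negative under all 4 other scalings. Among their members, miR-191-5p stood at 0.36, miR-24-3p at -0.03, miR-22-3p at -0.52, miR-30e-5p at 0.29, miR-146a-5p at -0.27, miR-125a-5p at -0.11 and miR-21a-5p at -0.08. miR-30d-5p and miR-30c-5p stood at 0.03 and 0.19, both negative under TMM.

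**Figure D3:**
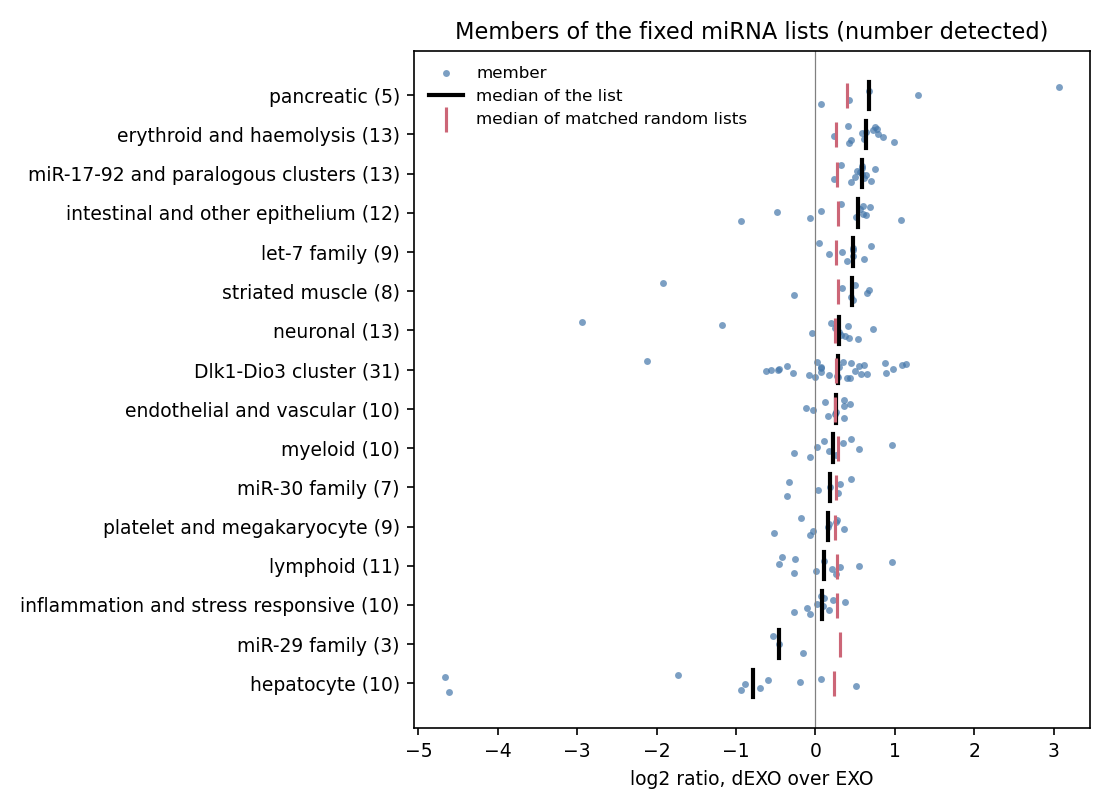
Log2 ratio of dEXO over EXO for each detected member (points) of the fixed miRNA lists, with the list median (black bar), the median of matched random lists (red tick) and the number of detected members in brackets. The hepatocyte median lies at -0.79 and the erythroid median at 0.63, against 0.24 and 0.26 for their random lists.

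The ratio of the 5p to the 3p arm of a hairpin was compared between the libraries because it does not depend on their scaling. Among 78 hairpins with at least 50 counts on each arm, the ratio of ratios dEXO over EXO had a median of 1.09 (quartiles 0.914 and 1.35). Its log2 values had an SD of 0.53 across hairpins, counting error included, against 0.65 for the log2 ratios of mouse miRNAs past the filter. The interval excluded 1 for 26 hairpins. For 4 of these the ratio of ratios was also at least 2 or at most 0.5, all with a larger 5p share in dEXO. mir-6240 stood at 5.26 (4.07 to 6.81), mir-26b at 2.87 (1.70 to 4.99), mir-195a at 2.22 (1.26 to 3.99) and mir-362 at 2.01 (1.27 to 3.21). The rarer arms of mir-26b, mir-195a and mir-362 held only 67, 60 and 100 counts over both libraries. The lowest were mir-142a at 0.615 (0.518 to 0.728), mir-200b at 0.617 (0.489 to 0.779) and mir-324 at 0.637 (0.401 to 1.01). Reads of miR-26b-5p, miR-142a-5p and miR-200b-3p were partly shared with other sequences, so their ratios are uncertain. With 20 counts on each arm 11 of 103 hairpins passed, and with 200 counts 1 of 43.

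Entries not named as mouse miRNAs were predicted hairpins, and they were scarcer in dEXO. They took 0.179% of dEXO counts (0.173 to 0.185%) and 0.628% of EXO counts (0.616 to 0.640%), 3.51-fold lower in dEXO (3.38 to 3.66). Of 117 distinct sequences 13 passed the filter, 8 of them at least 2-fold lower and none at least 2-fold higher. The 3 most abundant were PC-3p-352_3933 at 784 CPM in dEXO and 1536 in EXO, PC-5p-1133_1105 at 75.5 and 1147 CPM, and PC-5p-1940_615 at 479 CPM in EXO and 19.2-fold lower in dEXO (14.2 to 26.6).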

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

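The numbers of entries past 2-fold depended on the scaling and on the thresholds. Against 6 entries higher and 15 lower in dEXO in the main comparison, edgeR's TMM, DESeq2's size factors and the authors' normalized values each gave 1 higher and 20 lower, and the total without the 5 most abundant miRNAs gave 1 higher and 26 lower. Those 4 scalings lower every ratio by a common factor. The total without the 5 most abundant also raises the CPM values, so that more entries pass the filter, and these parts were not separated. No filter on low counts gave 80 higher and 112 lower, a mean of at least 500 CPM gave 4 higher and 4 lower, and mouse miRNAs alone gave 6 higher and 7 lower, all by construction of the sets counted. On the library total, the excess of lower entries was thus absent or nearly so in the last 2 of these sets. Among mouse miRNAs it returned under the 4 other scalings. There miR-5106 alone was higher, and miR-192-5p, miR-101b-3p and miR-5124a joined the lower ones. The 1.5-fold threshold gave 54 higher and 23 lower, and the 4-fold threshold 0 higher and 10 lower. With 1 row per sequence, not summed, an alternative chosen after seeing the data, 10 were higher and 15 lower, depth was 1570695 in dEXO and 1646118 in EXO, the 10 most abundant miRNAs held 40.1% and 48.5%, and predicted hairpins 0.199% and 0.682%, because this leaves out part of the reads. Arm ratios past 2-fold numbered 11 with 20 counts on each arm and 1 with 200, against 4. With 200 counts mir-26b, mir-195a and mir-362 dropped out, since their rarer arms held 67, 60 and 100 counts. The cause of the larger number with 20 counts was not tested. The number of lists outside percentiles 2.5 to 97.5 was 5 in the main comparison and under 7 alternatives, the same 5 lists in each. Of these alternatives, the 4 scalings shift all miRNAs together and so leave percentiles nearly unchanged by construction. With each row taken separately the number was 4, where the epithelial list left. The ratio of miR-451a to miR-23a-3p was 1.79-fold under both settings tried. Among 76 named entries, 11 had a log2 ratio of another sign under at least 1 setting, none of them past 2-fold. With 1 library per group, depth limits only counting error, and the spread between animals is unknown. No leave-one-out or DESeq2 replicate test was run. No paired analysis was possible because each group has 1 library.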

Other observations

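In the weighing of the 3 patterns below, the tests of the miR-122 pattern, the tests for reads of another organism and for transcript fragments and the test of the epithelial list were chosen after the results were seen, as was the scan of genomic clusters.

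A pair of genomic clusters had high median ratios in dEXO. A scan of mouse hairpins within 10 kb of each other on 1 strand gave 14 clusters with at least 4 miRNAs past the filter, of which 2 lay outside percentiles 2.5 to 97.5 of matched random lists, a range that 5% of random lists leave by chance. The chromosome X cluster of miR-322, miR-351, miR-450 and miR-503 (53047997 to 53054349, minus strand) had a median log2 ratio of 0.76 over 7 miRNAs (0.46 to 1.12, percentile 99.5). The miR-15b and miR-16-2 cluster in Smc4 on chromosome 3 stood at 0.71 over 4 miRNAs (0.62 to 1.01, percentile 99.3), but it is no separate observation, since miR-15b-5p and miR-16-5p are members of the erythroid list, and miR-16-5p shares its reads with a second locus. Both arms of a hairpin counted as separate members, and whether members of a cluster moved together was not tested.

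miR-122-5p was 24.6-fold lower in dEXO. The highest log2 ratio of miR-122-5p over 5 scalings was -4.62. That value cannot decide on scaling, since the other scalings moved the median of mouse miRNAs by only -0.20 to -0.23. A difference in scaling would shift all miRNAs alike, but 94.7% of 246 mouse miRNAs had log2 ratios between -1 and 1. Scaling is thus argued against. Capture or naming of 1 mature sequence is argued against too, since the other arm, miR-122-3p, had a ratio of 0.0342 (0.0169 to 0.0620). Dilution by red cell RNA would have lowered the other miRNAs too, but the median log2 ratio of 231 mouse miRNAs outside the erythroid list was 0.26 (quartiles 0.02 and 0.52). A lower share of hepatocyte RNA in dEXO, or a higher one in EXO, may be involved, since the hepatocyte list without miR-122 had a median log2 ratio of -0.65 over 8 members, percentile 0.02 of matched lists, a far smaller difference than that of miR-122, with miR-101a-3p at -0.20, miR-802-5p at 0.07 and miR-194-5p at 0.51. Whether this goes with antibiotic treatment, with 1 animal or with blood collection was not tested, with 1 library per group.

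Predicted hairpins were 3.51-fold scarcer in dEXO, and of 65 with at least 20 counts 59 were lower there. Of the 117 sequences, 5.13% lay within 2 mismatches of a measured mouse miRNA. Close variants carry the name of their mouse miRNA with a suffix, so few could be listed as predicted. Whether variants are a source thus cannot be told from this share. In annotated mouse transcripts, 4.27% were found with at most 1 mismatch, against 5.98% of the same sequences reversed. That argues against fragments of these transcripts as the source of the listed sequences, though reads of other RNA families were filtered out beforehand. The search found 73.3% of the 60 known mouse sequences that differ from their hairpin, but 395 of 399 mouse precursor positions are themselves annotated. Reads of another organism may contribute: 92.3% of the sequences differed by 1 base from their own mouse hairpin, against 11.3% of known mouse sequences. Their median length was 19 nt against 22 nt. The 108 predicted sequences with a mismatch had a ratio of 0.282 (0.270 to 0.293). The 9 without one were also lower in dEXO, at 0.469 (0.360 to 0.608), on 87 counts in dEXO and 189 in EXO. The 60 known mouse sequences with a mismatch had a ratio of 1.21 (1.20 to 1.22). A mismatch alone thus did not go with a lower share in dEXO, and the source cannot be told from it. Mouse ribosomal repeats outside the annotation and sequencing errors in such repeats were not searched and stay open, and no other genome was compared here.

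miR-192-5p and miR-215-5p went in opposite directions, with log2 ratios of -0.94 and 1.08. Reads shared between these paralogs are argued against, since the detected sequences differed by 4 bases at their best alignment and miR-215-3p stood at 1.06. More intestinal epithelial RNA in dEXO could be involved, but the epithelial list without miR-192, miR-194 and miR-215 lay at percentile 97.375, just short of 97.5, so this cannot be told apart from no shift of epithelial RNA with 9 members. An effect of the antibiotics on these loci stays untested.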
